A study of Homo sapiens with 6 samples.

How the data were processed

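Total RNA of A375 cells, a human melanoma cell line, was measured on 6 Affymetrix expression arrays. Per the labels, 3 arrays held A375 cells without a knockdown (control) and 3 held A375 cells with a stable short hairpin RNA against MAP4K5 (knockdown). All 6 are described as biological replicates, and the labels do not say how the cultures were separated in time, so p-values measure the spread between these arrays. Whether the control cells carried a control vector, and the sequence of the hairpin, are not given in the sources used here. Per the labels' protocols, cells were grown without treatment, RNA was extracted with Trizol, and biotin-labelled cRNA was prepared by the manufacturer's standard protocol.

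The deposited values are probe set intensities on a linear scale, summarised by RMA per the submitters' processing notes, with no version given in the sources used here. Linearity was read from the values, which ran from 1.55 to 6658 with none below 0. RMA corrects background, normalizes quantiles across arrays and summarises the probes of a set, and it compresses fold changes of dim probe sets. Median intensities per array lay between 4.85 and 4.94, and the sorted log2 values of an array departed from the mean of all arrays by at most 0.09. No detection calls or bead or read counts enter these values, so the number of arrays limits the precision. No pair of arrays was a copy of another: the SD of the log2 difference between 2 arrays was at least 0.172. No scan date or batch is given in the sources used here.

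Log2 of the deposited intensity was taken here without a pseudocount. The table held 49293 probe sets, and the platform annotation paired 44988 with 1 gene symbol, 1832 with several and 2473 with none. Only probe sets with 1 symbol were used for genes. Symbols were checked through Entrez identifiers against the RefSeq gene table of GRCh38.p14, which changed 0 symbols, and 27 probe sets kept the platform's symbol because the identifier was not matched. For each gene the probe set with the highest mean over all 6 arrays was taken, which left 18132 genes, 11734 of them with more than 1 probe set. No filter on dim genes was applied. The median gene mean was 8.68 in intensity. The build of the array annotation is not given in the sources used here, so no coordinates are printed, and the RefSeq table served only for names and for the order of neighbouring genes.

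Knockdown was compared with control by limma (version 3.58.1, R 4.3.3; lmFit and eBayes without a trend), with Benjamini-Hochberg adjustment over all 18132 genes and a threshold of 0.05. All fold changes are knockdown minus control on the log2 scale, with the standard error (SE) of the fit. Counts with an absolute log2 fold change of at least 1 are given beside the full counts. MAP4K5 was also compared per probe set with an exact two-sided permutation test, whose smallest possible p with 3 arrays against 3 is 0.1. A set of 29 gene lists, written from general knowledge, was tested with limma's camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Of 662 list entries, 605 were measured, 2 of them under a newer symbol. Camera with an estimated correlation, fry and camera on ranks were run beside it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for the other steps.

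The groups, the tests, the lists, the rule for naming genes and the alternatives were fixed before the data were examined, except the fits of the knockdown arrays against each control array alone and the tests named in the closing section as chosen later. The rule named MAP4K5 first. It then took the 12 largest rises and the 12 largest falls among genes past the test whose groups did not overlap and whose higher group mean reached the median of gene means. Of each list it took up to 2 members with the largest rise and 2 with the largest fall among those past the test, or the member with the smallest p where none passed. Other alternatives were the replicate number as a block, an intensity trend, array weights, shifting arrays to a common median, repeated quantile normalization, leaving out the lowest 25% or 50% of genes by mean, the mean of a gene's probe sets, leaving out probe sets with IDs ending in _x_at or _s_at (which can bind several transcripts), a test per probe set, limma's treat against a log2 change of 0.5, and leaving out each array in turn. A lone remaining control array was assumed to vary like the knockdown arrays. The control arrays varied more: the SD of the log2 difference was 0.20 to 0.32 between 2 controls and 0.17 between 2 knockdown arrays. Adjusted p-values of those fits hold no spread between controls and can be too small, so their effect sizes are given without them. The planned check of RNA integrity from control probe sets was not run, since 0 probe sets of the table used here carried the control prefix.

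The gene and list steps were tested on simulated arrays with 18132 genes in the layout of the knockdown comparison. The gene test recovered 34.3% of genes changed by 0.5, 88.1% of those changed by 1 and 100% of those changed by 2 on the log2 scale, and called 6 of 17932 unchanged genes. A list shifted by 0.5 was called by each of the set tests tried there, preset camera, camera with an estimated correlation and fry. The simulated genes were drawn independently and no array was set apart from its group. Lists whose members move together were therefore not tried, and these rates need not hold for them.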

Results

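Gene expression was profiled on 6 arrays, 3 of A375 melanoma cells (control) and 3 of A375 cells with a stable knockdown of MAP4K5, a kinase of the germinal centre kinase family that acts upstream of the JNK pathway. The comparison asks which transcripts differ between the knockdown cells and the control cells. Other effects of the hairpin, or of making the stable line, cannot be told apart from loss of MAP4K5 in this design. Levels are RMA intensities, with median intensities per array between 4.85 and 4.94.

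MAP4K5 itself was lower in all 3 knockdown arrays. At the brightest of its 3 probe sets, the level was 77.4 ± 0.95 in control and 19.6 ± 0.74 in knockdown cells (SD, n = 3 each), a 3.95-fold decrease that left 25.3% of the control level. The log2 fold change was -1.98 ± 0.08 (SE), with a limma adjusted p of 2.9e-05. The other probe sets fell 4.47-fold and 3.05-fold. Each gave an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow.

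**Figure D1:**
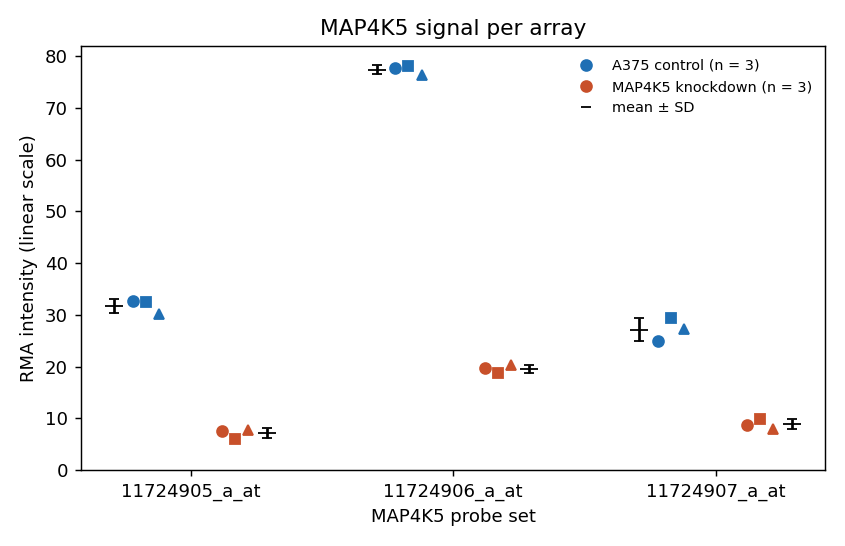
MAP4K5 intensity (linear RMA scale, vertical axis starting at 0) of each array at its 3 probe sets (horizontal axis), with group means and SD of n = 3 and marker shapes for replicates 1 to 3 of each group. At each probe set all 3 knockdown arrays lie below all 3 control arrays, and control replicate 2 stands at 78.1 at the brightest probe set, at the level of the other controls.

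The control arrays were not alike. Control replicate 2 correlated with the knockdown arrays at 0.993 to 0.994 over all genes and with the other controls at 0.992, while control replicates 1 and 3 correlated with each other at 0.997. On the first principal component, which held 63.9% of the variance, controls 1 and 3 scored -29.94 and -28.19, control 2 -0.32 and the knockdown arrays 17.88 to 21.04. These correlations run across genes, which are not independent replicates. The level of control replicate 2 is given beside each gene group that shifted.

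Among the genes that rose, PKIB, an inhibitor of cAMP-dependent protein kinase, rose the most, 7.65-fold (log2 2.94 ± 0.25 SE, limma adjusted p = 0.000726, n = 3 per group). The secreted glycoprotein gene STC1 rose 6.42-fold (2.68 ± 0.14), and NEFL, the light neurofilament chain, rose 5.96-fold (2.58 ± 0.36). The collagenase MMP1 and the stromelysin MMP3 rose 4.45-fold (2.15 ± 0.20) and 4.17-fold (2.06 ± 0.27). Mean intensities in control cells of PKIB (5.88), LRRC17 (6.40), MMP1 (4.80) and MMP3 (3.73) lay below the median gene, at 8.68, where RMA compresses folds. NEFL stood at 1.63 without probe sets ending in _x_at or _s_at. The membrane protein gene MAL2 (2.23), the TNF family ligand TNFSF9 (2.19), the matricellular protein gene CCN3 (2.01), the long non-coding RNA UCA1 (2.01), the secreted leucine-rich repeat protein gene LRRC17 (2.40) and the histone genes H2BC5 (1.95) and H2BC12 (1.86) completed the 12 largest rises.

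Among the genes that fell, HMCN1, which encodes an extracellular matrix protein, was 9.63-fold lower in knockdown cells (log2 -3.27 ± 0.22 SE, limma adjusted p = 0.000312, n = 3 per group). MGP, an inhibitor of calcification, was 6.99-fold lower (-2.81 ± 0.13), and TFAP2B, a transcription factor of the neural crest, 6.27-fold lower (-2.65 ± 0.14). TMEM47 (-2.57), the cadherin gene CDH19 (-2.38), the matrix protein gene ABI3BP (-2.32), the axonal adhesion gene CNTN4 (-2.18), the immediate early transcription factor EGR1 (-1.99), GAS7 (-1.93) and the MHC class II chain HLA-DQA1 (-1.93) also fell. NFATC2, a calcium-regulated transcription factor, fell by 3.03, but the fold change was -0.20, not called, without probe sets ending in _x_at or _s_at. MAP4K5 was the remaining member of the 12 largest falls. Not all probe sets were called for NFATC2 (1 of 3), EGR1 (1 of 6), HLA-DQA1 (1 of 4), GAS7 (2 of 6), CNTN4 (1 of 2), MGP (1 of 2) and, among the rises, H2BC12 (1 of 2). Mean intensities in knockdown cells of HMCN1 (3.34), MGP (3.55), ABI3BP (3.31), CNTN4 (2.97), TFAP2B (6.04), TMEM47 (6.25) and NFATC2 (8.07) lay below the median gene, so their folds carry the same limit.

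Of these 24 genes, 20 kept their call in each of 6 fits that left out 1 array. LRRC17 lost it without knockdown replicate 1 or 2, with fold changes of 2.08 to 2.91 over the 6 fits, and HLA-DQA1 lost it without control replicate 1 or any knockdown array (-2.37 to -1.59). CNTN4 (-2.96 to -1.75) and EGR1 (-2.66 to -1.61) kept it only without control replicate 2, and against control replicate 2 alone they stood at -0.63 and -0.65. LRRC17 and HLA-DQA1 stood at 1.36 and -1.05 against it.

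**Figure D2:**
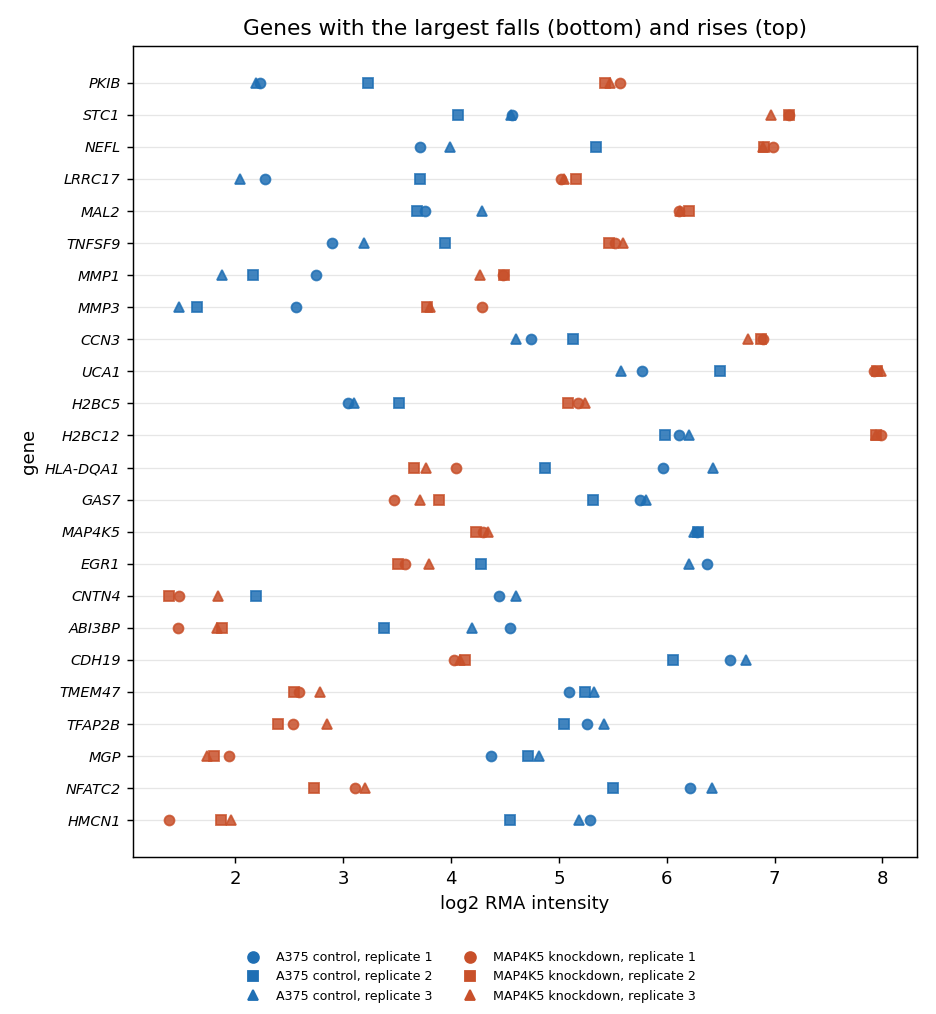
Log2 RMA intensity (horizontal axis) of the 24 genes with the largest rises and falls (vertical axis), with each of the 6 arrays as a point, coloured by group and shaped by replicate. For every gene plotted the 3 knockdown points lie on 1 side of the 3 control points, and for LRRC17, CNTN4, EGR1 and HLA-DQA1 control replicate 2 lies nearer to the knockdown points than to the other controls.

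Over all 18132 genes, limma called 1420 at an adjusted p under 0.05, of which 671 rose and 749 fell. Of these, 179 changed at least 2-fold, 69 upwards and 110 downwards. In all 1420 the groups did not overlap, as in 28.1% of all genes, where chance gives 10%. The count was 3732 without control replicate 2, 522 without control 1, 565 without control 3, and 324, 371 and 392 without knockdown replicates 1, 2 and 3. The 2-fold count was 393 without control 2 and 113 without knockdown 1. A core of 286 genes, 121 up and 165 down, was called in the full fit and in each fit without 1 array. Fits against each control array alone were chosen after the controls were seen to differ. Their counts of called genes are not given, since they hold no spread between controls.

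Of the 29 gene lists, 10 shifted by camera at a preset correlation, 4 upwards and 6 downwards. With an estimated correlation 0 of the 29 passed. The estimate was 0.75 for the DNA replication list, 0.82 for mitosis and 0.37 for the stress response, against the preset 0.01. Camera with an estimated correlation was run only on the full fit. List adjusted p-values of the fits without 1 array use the preset and can be far too small where members move together. By fry, which asks whether genes move on balance 1 way and does not compare a list with other genes, 7 passed: the epithelial, hypoxia, invasive melanoma, integrin, MAP4K family, p53 and TGF-beta lists. The MAP4K family list holds the targeted gene MAP4K5 itself, and its median log2 fold change was -0.0024. Fry gave the p53 list as upwards with a mean of -0.07, and the TGF-beta list as downwards with a mean of 0.01. Of the 81 genes named under the rule that passed the test, 41 did not have all their probe sets called in the test per probe set. None had a probe set called in the opposite direction. The remaining called members of the shifted lists were named after their values were seen. Of the called genes named here, HLA-DQA1, HLA-DPA1, MMP3, SPRY4, IER3, P4HA1, ZEB1, KRT14, KRT18 and the histone genes H1-2 and H2AC6 were read only by probe sets ending in _x_at or _s_at, so no value remained without these. The called genes ATF2, EBP, GINS3, PRRX1, PARP9 and FJX1 had 0 probe sets called in the test per probe set. Over all 605 measured list entries, 39 rose and 61 fell in the full fit, against 115 and 147 without control replicate 2, 20 and 32 without control 1, 19 and 36 without control 3, and 13 and 24, 16 and 27, and 14 and 29 without knockdown 1, 2 and 3.

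Genes of DNA replication and the E2F response rose as a list, with a mean log2 fold change of 0.37 over 27 measured genes (camera adjusted p = 2.1e-05; adjusted p = 0.552 with an estimated correlation). Of the members, 3 rose and 24 were not called, and 5 rose adjusted over the list alone. Without control replicate 2, 19 rose (mean 0.54, camera adjusted p = 5.31e-12 at the preset correlation of 0.01, against an estimate of 0.75 in the full fit). Those that rose in the full fit were E2F2 (0.66 ± 0.15 SE), an E2F transcription factor, the replisome subunit GINS3 (0.49 ± 0.12) and the replication licensing factor CDT1 (0.40 ± 0.10). Among the fits without 1 array, the calls of E2F2, GINS3 and CDT1 held only without control replicate 2 (fold changes 0.52 to 0.75, 0.36 to 0.60 and 0.34 to 0.48 over the 6 fits). E2F2 stood at -0.20 without probe sets ending in _x_at or _s_at. GINS3 and CDT1 kept their probe sets and fold changes there. They lost their calls narrowly (limma adjusted p = 0.0535 and 0.0546) in that fit over 16701 genes. Relative to the mean of all arrays, the list stood at 0.17 in control 2, at -0.37 and -0.35 in controls 1 and 3, and at 0.17 to 0.19 in the knockdown arrays. Against control 2 alone the shift was 0.02.

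Genes of mitosis and proliferation followed, with a mean of 0.22 over 25 genes (adjusted p = 0.0318; adjusted p = 0.688 with an estimated correlation), and 0 members were called, over all genes or adjusted over the list alone. The mitotic kinesin KIF23 had the smallest p, at 0.70 ± 0.18 (limma adjusted p = 0.0502), and passed without control replicate 2, where 14 members rose and the list mean was 0.41 (adjusted p = 2.57e-08). Control 2 held the highest list level, 0.28, against 0.09 to 0.12 in the knockdown arrays. Against control 2 alone the list mean was -0.17, opposite in sign to the full fit. The list call was lost without control 1 (0.14), control 3 (0.10) or knockdown replicate 2 (0.21), and with the lowest 25% or 50% of genes left out (adjusted p = 0.055 and 0.0876). Cholesterol biosynthesis genes rose by a mean of 0.27 over 18 genes (adjusted p = 0.0153; adjusted p = 0.552 with an estimated correlation). The sterol isomerase EBP (0.68 ± 0.17) and the lanosterol synthase LSS (0.47 ± 0.09) rose, also adjusted over the list alone, and the other 16 were not called. Both gene calls held only without control replicate 2 among the leave-one-out fits, with ranges of 0.53 to 0.89 and 0.40 to 0.52, and without it 11 members rose (mean 0.43, adjusted p = 8.5e-06). LSS stood at 0.34, not called (adjusted p = 0.206), without probe sets ending in _x_at or _s_at. The list stood at 0.18 in control 2, -0.30 and -0.29 in controls 1 and 3 and 0.11 to 0.15 in knockdown cells. It was lost without control 3 (0.19, camera adjusted p = 0.0833) or with the lowest 50% of genes left out (adjusted p = 0.0853). Its mean was -0.04 against control 2 alone.

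Genes of the unfolded protein and integrated stress responses fell as a list, with a mean log2 fold change of -0.71 over 24 genes (camera adjusted p = 0.000402; adjusted p = 0.52 with an estimated correlation). PHGDH, the entry enzyme of serine synthesis, fell by 1.28 ± 0.29 (SE), and the endoplasmic reticulum protein gene SDF2L1 rose by 0.77 ± 0.17. The other 22 were not called, while adjusted over the list alone 1 rose and 11 fell. Without control replicate 2, 2 rose and 17 fell (mean -1.05, adjusted p = 1e-11). Both gene calls held only without control replicate 2 (-1.68 to -1.04 and 0.63 to 0.99). Among members named after their values were seen, DDIT3, a transcription factor of the stress response, measured 89.4 and 102.2 in controls 1 and 3, 8.6 in control 2 and 8.0 to 9.5 in knockdown cells (log2 -2.29 ± 0.81, adjusted p = 0.131). ASNS, asparagine synthetase, measured 1427 and 1562 in controls 1 and 3, 320.6 in control 2 and 222.2 to 238.4 in knockdown cells (log2 -1.94 ± 0.52, adjusted p = 0.0587). The list stood at 0.66 and 0.73 in controls 1 and 3, at -0.32 in control 2 and at -0.38 to -0.34 in knockdown cells. Its shift was -0.04 against control 2 alone.

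NF-kB target genes fell by a mean of 0.25 on the log2 scale over 20 genes (adjusted p = 0.000578; adjusted p = 0.52 with an estimated correlation). The chemokines CXCL8 (-0.79 ± 0.11 SE) and CXCL1 (-0.50 ± 0.11), the subunit gene NFKB1 (-0.54 ± 0.11) and the adaptor TRAF1 (-0.46 ± 0.10) fell. TNFAIP3, a ubiquitin-editing inhibitor of the pathway, rose 3.21-fold (1.68 ± 0.10), and 15 genes were not called. Adjusted over the list alone, 8 fell and 1 rose, and without control replicate 2, 11 fell and 1 rose. TNFAIP3 and CXCL8 were called in all 6 fits without 1 array, NFKB1 only without control 2 (-0.66 to -0.45), CXCL1 only without control 1 or 2 (-0.59 to -0.39) and TRAF1 only without control 2 or knockdown 3 (-0.54 to -0.39). TNFAIP3 stood at 1.09 and CXCL1 at -0.27, not called, without probe sets ending in _x_at or _s_at. The list stood at -0.07 in control 2, 0.20 and 0.25 in controls 1 and 3 and -0.17 to -0.09 in knockdown cells. Its shift was -0.06 against control 2 alone.

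ERK pathway output genes fell by a mean of 0.29 over 19 genes (adjusted p = 0.00586; adjusted p = 0.52 with an estimated correlation). EGR1, the feedback inhibitors SPRY4 (-1.13 ± 0.18 SE) and SPRY2 (-0.65 ± 0.10), the transcription factor MYC (-0.87 ± 0.21) and IER3 (-0.33 ± 0.08) fell. The ERK phosphatase DUSP4 (0.56 ± 0.09) and the receptor kinase EPHA4 (0.74 ± 0.15) rose, and 12 genes were not called. Adjusted over the list alone, 9 fell and 2 rose, and without control replicate 2, 10 fell and 2 rose. SPRY4 (-1.34 to -0.99) and DUSP4 (0.50 to 0.61) lost their calls without knockdown replicate 1 or 3, and EPHA4 (0.56 to 0.87) without control 3 or any knockdown array. SPRY2 (-0.74 to -0.60) lost its call without knockdown 1 or 2. EGR1 (-2.66), MYC (-1.14) and IER3 (-0.36) kept theirs only without control 2, the value given. Control 2 stood at -0.09, controls 1 and 3 at 0.26, and knockdown arrays at -0.16 to -0.13. The shift was -0.06 against control 2 alone.

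Antigen presentation genes fell by a mean of 0.29 over 19 genes (adjusted p = 0.0139; adjusted p = 0.52 with an estimated correlation). The 4 that fell, the class II chains HLA-DRA (-1.36 ± 0.16 SE) and HLA-DPA1 (-0.96 ± 0.13), the invariant chain CD74 (-0.99 ± 0.17) and the peptide loading chain HLA-DMA (-0.93 ± 0.19), belong to the class II pathway. The count was also 4 adjusted over the list alone and 8 without control replicate 2, and 15 genes, the class I genes among them, were not called. HLA-DRA kept its call in all 6 fits without 1 array but stood at 0.14 without probe sets ending in _x_at or _s_at, CD74 kept it only without control 2 or 3 (-1.19 to -0.82) and HLA-DMA only without control 1 or 2 (-1.06 to -0.74). The list stood at 0.02 in control 2, 0.15 and 0.26 in controls 1 and 3 and -0.17 to -0.13 in knockdown cells, and was lost without control 3 (-0.23, adjusted p = 0.0554) and without probe sets ending in _x_at or _s_at (-0.15, adjusted p = 0.283). Its mean was -0.17 against control 2 alone.

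Hypoxia and glycolysis genes fell by a mean of 0.20 over 29 genes (adjusted p = 0.0318; adjusted p = 0.52 with an estimated correlation), with 5 members lower and 24 not called. The aldolase ALDOC (-1.13 ± 0.15 SE), the pyruvate dehydrogenase kinase PDK1 (-0.88 ± 0.13), the collagen prolyl hydroxylase subunit P4HA1 (-0.58 ± 0.08), the mitophagy gene BNIP3 (-0.57 ± 0.10) and the hexokinase HK2 (-0.36 ± 0.08) fell, and adjusted over the list alone 9 fell and 1 rose, and without control replicate 2, 9 fell and 4 rose. ALDOC, PDK1 and P4HA1 were called in all 6 fits without 1 array, BNIP3 was lost without any 1 knockdown array (-0.64 to -0.47), and HK2 was called only without control 2 (-0.39 to -0.34). ALDOC stood at -0.40 and BNIP3 at -0.12, neither called, without probe sets ending in _x_at or _s_at. On this list control 2 (0.10) lay with controls 1 and 3 (0.14 and 0.07), away from the knockdown arrays (-0.12 to -0.09). The list was lost without control 2 (-0.20, adjusted p = 0.177), and its mean against control 2 alone was also -0.20. It was also lost with array weights (adjusted p = 0.0979), with the lowest 25% or 50% of genes left out (0.055 and 0.0853) and by camera on ranks (0.131).

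Invasive or dedifferentiated melanoma genes fell by a mean of 0.11 over 22 genes (adjusted p = 0.0496; adjusted p = 0.52 with an estimated correlation). The repressor of epithelial genes ZEB1 (-0.85 ± 0.08 SE), the matrix protein TNC (-0.80 ± 0.11), WNT5A (-0.67 ± 0.16), FGF2 (-0.49 ± 0.11) and TGFBI (-0.40 ± 0.09) fell. SOX9, a transcription factor of neural crest and cartilage, rose 3.13-fold (1.65 ± 0.14), and 16 genes were not called. Adjusted over the list alone, 5 fell and 2 rose. ZEB1, TNC and SOX9 were called in all 6 fits without 1 array, FGF2 (-0.62 to -0.42) and TGFBI (-0.48 to -0.35) only without control 2, and WNT5A (-0.80 to -0.49) only without control 2 or 3. The list was lost without control 2 (-0.09), control 3 (-0.12) or knockdown replicate 1 or 2 (-0.10 each). It was also lost after repeated quantile normalization (adjusted p = 0.0512), with array weights (0.0979), with the lowest 25% or 50% of genes left out (0.0779 and 0.113), without probe sets ending in _x_at or _s_at (0.136) and by camera on ranks (0.129). Against control 2 alone the list mean was -0.17. Control 2 stood at 0.11 and controls 1 and 3 at 0.02 and 0.04, with knockdown arrays at -0.09 to 0.0017.

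Epithelial and keratinocyte markers rose by a mean of 0.23 over 17 genes (adjusted p = 0.0496; adjusted p = 0.52 with an estimated correlation). The keratins KRT15 (1.24 ± 0.11 SE), KRT14 (1.09 ± 0.16) and KRT18 (0.69 ± 0.09) and the desmosome genes DSP (0.72 ± 0.09) and PKP3 (0.48 ± 0.10) rose, KRT7 fell by 0.81 ± 0.18, and 11 were not called. The counts were the same adjusted over the list alone. KRT15 and KRT14 went from 5.90 to 13.9 and from 6.02 to 12.8 in mean intensity, near the median gene at 8.68, and 6 of the 17 markers had means at or above that median. KRT15, KRT14, KRT18 and DSP were called in all 6 fits without 1 array, KRT7 only without control 2 (-1.0007 to -0.61) and PKP3 only without control 2 or 3 (0.39 to 0.56). DSP stood at 0.30, not called, without probe sets ending in _x_at or _s_at. The list was lost without control 1 (0.20), control 2 (0.26), control 3 (0.24) or knockdown replicate 2 (0.22). It was also lost after repeated quantile normalization (adjusted p = 0.0512), with an intensity trend (0.0539), with array weights (0.0592), without probe sets ending in _x_at or _s_at (0.283) and by camera on ranks (0.224). Against control 1, 2 and 3 alone the list mean was 0.30, 0.19 and 0.22. Control 2 stood at -0.07, controls 1 and 3 at -0.18 and -0.10, and knockdown arrays at 0.10 to 0.15. Markers of other cell types were not called as lists. Of 16 fibroblast markers, 9 of them also in other lists, PRRX1 fell (-0.77, called only without control 2 among the leave-one-out fits, -0.996 to -0.62) and 15 were not called (list adjusted p = 0.39). PRRX1 was called at 0 of 2 probe sets and was -0.65, not called (adjusted p = 0.22), without probe sets ending in _x_at or _s_at. Of 17 blood and endothelial markers, LYZ rose (0.97 ± 0.13, called at 1 of 2 probe sets, and 0.45 without probe sets ending in _x_at or _s_at) and 16 were not called (list adjusted p = 0.54).

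**Figure D3:**
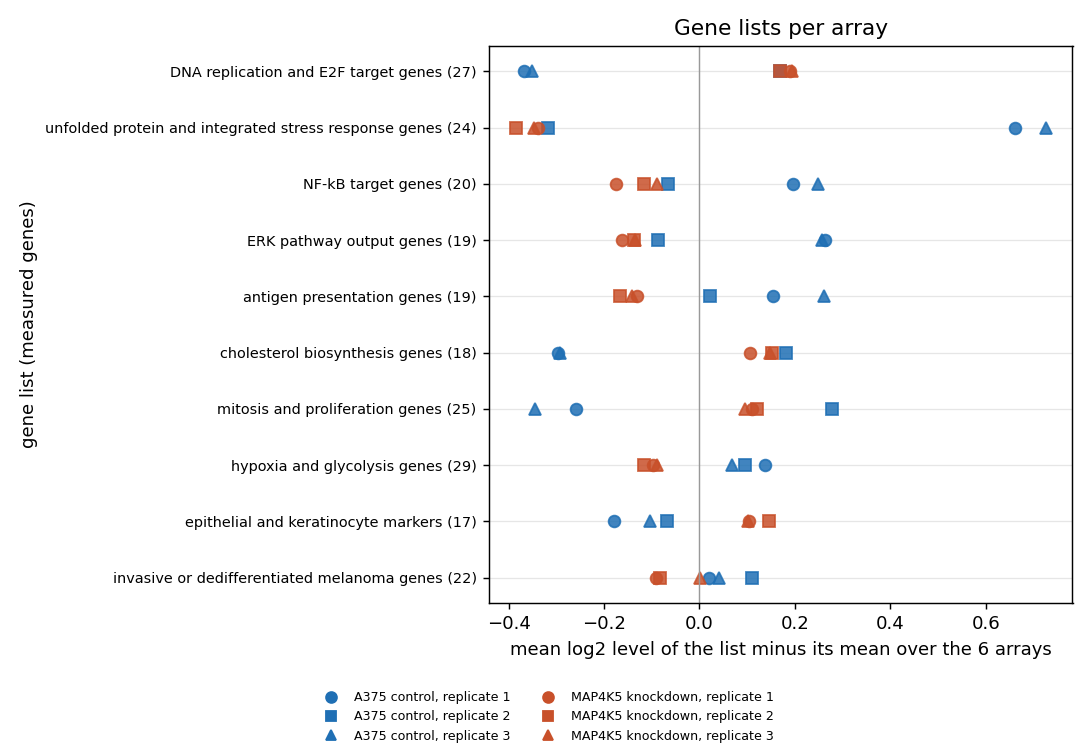
Mean log2 level of each of the 10 shifted gene lists per array, minus its mean over the 6 arrays (horizontal axis, log2 units), with the number of measured genes after each list name (vertical axis), colours for groups and shapes for replicates. Control replicate 2 stands at -0.32, just above the knockdown arrays (-0.38 to -0.34), for the stress response genes, and at 0.10 with the other controls for hypoxia and glycolysis genes.

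Melanocyte differentiation genes did not shift as a list (adjusted p = 0.679), with 3 of 21 higher, 3 lower and 15 not called (3 and 5 adjusted over the list alone). MITF, the central transcription factor of melanocytes, rose 1.99-fold (0.99 ± 0.16 SE, adjusted p = 0.0114) and lost its call without any 1 knockdown array (0.87 to 1.20), and CDK2 rose by 0.64 ± 0.16. The receptor kinase ERBB3 fell by 1.34 ± 0.14 and the endothelin receptor EDNRB by 0.91 ± 0.10, but ERBB3 stood at 0.10 without probe sets ending in _x_at or _s_at. CDK2 was called only without control 2 among the leave-one-out fits (0.47 to 0.79). Among receptor tyrosine kinases (adjusted p = 0.252) 1 of 27 rose and 3 fell (2 and 3 adjusted over the list alone), including the collagen receptor DDR2 at -1.43 ± 0.34, called only without control 2 (-1.92 to -1.18).

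Among collagens, matrix proteins and matrix proteases 4 of 36 rose and 6 fell (5 and 10 adjusted over the list alone; list adjusted p = 0.101), with the gelatinase MMP2 at -0.93 ± 0.09 SE beside the rises of MMP1 and MMP3. Of 16 integrins (adjusted p = 0.0951), 1 rose and 4 fell (1 and 5 adjusted over the list alone), with ITGA2 at 0.60 ± 0.12, ITGA4 at -0.91 ± 0.15 and ITGA9 at -0.89 ± 0.13. ITGA2 lost its call without control 3 or any knockdown array (0.45 to 0.69) and ITGA4 without knockdown 1 or 3 (-1.02 to -0.77). Of 22 cadherin, adhesion and EMT genes (adjusted p = 0.136), 1 rose and 3 fell (1 and 4 adjusted over the list alone). CDH11 stood at 1.41 ± 0.23, called at 1 of 6 probe sets and lost with the mean of its probe sets (0.28) or without knockdown 1 or 3 (1.27 to 1.70), and the tight junction gene CLDN1 at -1.57 ± 0.37, called only without control 2 (-2.05 to -1.28).

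Of the kinase lists around MAP4K5, 1 of 5 measured MAP4K family genes fell, MAP4K5 itself, as adjusted over the list alone (list adjusted p = 0.158). Of 22 JNK and p38 cascade genes (adjusted p = 0.621), the adaptor CRKL rose (0.50 ± 0.10 SE) and the JNK scaffold SPAG9 fell (-0.41 ± 0.08), both called only without control 2 (0.45 to 0.59 and -0.43 to -0.38), with 2 higher and 1 lower adjusted over the list alone. Of 15 AP-1 and ATF subunits (adjusted p = 0.39), MAF fell (-0.86 ± 0.11), and ATF2 (-0.40 ± 0.10) fell but was called only without control 2 (-0.48 to -0.34) and stood at 0.08 without probe sets ending in _x_at or _s_at. The count for this list was 2 lower in both adjustments, over all genes and adjusted over the list alone.

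Of 15 Wnt target genes (adjusted p = 0.126), the transcription factor LEF1 (-1.25 ± 0.10 SE) and the receptor TNFRSF19 (-1.44 ± 0.17) fell together with MYC, and the secreted inhibitor DKK1 rose (0.79 ± 0.16, called only without control 2, 0.66 to 0.99), the same counts as adjusted over the list alone. LEF1, called at 3 of 9 probe sets, stood at -0.65 and TNFRSF19 at -0.89 without probe sets ending in _x_at or _s_at. Of 24 YAP and TAZ targets (adjusted p = 0.448), F3, tissue factor, rose (1.46 ± 0.12), FJX1 rose (0.49 ± 0.11, called only without control 2, 0.42 to 0.61) and RBMS3 fell (-0.78 ± 0.16, called only without control 2 or 3, -0.91 to -0.61), with the same counts adjusted over the list alone. Of 15 TGF-beta response genes (adjusted p = 0.833), 0 rose and 3 fell (2 and 3 adjusted over the list alone), among them the pseudoreceptor BAMBI (-0.94 ± 0.09) and SMAD7 (-0.49 ± 0.09, called only without control 2, -0.55 to -0.43).

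Of 22 p53 targets (adjusted p = 0.475), 5 rose and 1 fell (7 and 4 adjusted over the list alone), with the death receptor FAS at 0.96 ± 0.12 SE, the exonuclease AEN at 0.71 ± 0.09 and CCNG1 at -0.50 ± 0.09, the last lost without control 1 or knockdown 1 or 3 (-0.56 to -0.45). Of 20 apoptosis regulators (adjusted p = 0.884), BAD alone rose (0.43 ± 0.10, called only without control 2, 0.33 to 0.48), as adjusted over the list alone. Of 33 type I interferon response genes (adjusted p = 0.931), 3 rose and 2 fell (6 and 4 adjusted over the list alone). SAMD9 (0.67 ± 0.12) and PARP9 (0.54 ± 0.13) rose, called only without control 2 (0.59 to 0.81 and 0.39 to 0.66). PARP9 was lost (limma adjusted p = 0.0504) without probe sets ending in _x_at or _s_at, with its own probe set and fold change kept. IFITM1 (-1.02 ± 0.17) and DDX60 (-0.60 ± 0.09) fell. IFITM1 was called only without control 2 or knockdown 3 (-1.20 to -0.91), and DDX60 was lost without knockdown 1 or 2 (-0.68 to -0.56).

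Of 19 oxidative stress genes (adjusted p = 0.423), the malic enzyme ME1 (-0.62 ± 0.09 SE) and AKR1C2 (-0.75 ± 0.16, called only without control 2 or 3, -0.91 to -0.58) fell, and 4 fell adjusted over the list alone. Against control 2 alone the mean of this list was -0.19. No oxidative phosphorylation gene of 27 (list adjusted p = 0.54) and no cancer-testis antigen of 13 (list adjusted p = 0.242) was called by limma, over all genes or adjusted over the list alone. The smallest p values there belonged to NDUFV2 (0.29 ± 0.09, adjusted p = 0.0796) and MAGEC2 (0.24 ± 0.08, adjusted p = 0.094), both called without control 2. Test, mean and median differed in sign for 4 lists that were not called. The TGF-beta list was tested downwards with a mean of 0.01 and a median of 0.05, the p53 list upwards with a mean of -0.07, the oxidative stress list downwards with a median of 0.02, and the apoptosis list upwards with a mean of -0.02.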

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

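The fits against each control array alone were chosen after the data were seen; the other settings were fixed beforehand. MAP4K5 kept its direction and its call in every gene-level fit made with it, with log2 fold changes of -2.01 to -1.92, and at each of its 3 probe sets, with -2.16 to -1.61. Changing the scaling, the variance trend or the filter on dim genes kept the counts of called genes within 1.5 times of 1420. The replicate number as a block gave 1188 genes and 10 lists, and the block ended the calls of ATF2, BAD, E2F2, PARP9 and FJX1. Deviations from the group means correlated between arrays of the same number at only -0.08, 0.02 and 0.06, so no shared effect of the number was seen. So few arrays cannot exclude that the numbers mark paired cultures. The count was 3103 with array weights, where control replicate 2 had the lowest weight at 0.34, 2186 with a test per probe set and 70 by treat, and 324 to 3732 without 1 array. It was 2981, 428 and 2489 against control 1, 2 and 3 alone. Genes changed at least 2-fold numbered 179 in the full fit, 309 with array weights, 75 with the mean of a gene's probe sets, 320 per probe set, 68 by treat, 113 to 393 without 1 array, and 429, 117 and 412 against control 1, 2 and 3 alone. The lists called numbered 10 in the full fit, 5 to 10 without 1 array and 0 with an estimated correlation. Against control 2 alone, the mitosis list (-0.17) and the cholesterol list (-0.045) changed direction. Without probe sets ending in _x_at or _s_at, HLA-DRA (0.14), ATF2 (0.076), E2F2 (-0.20) and ERBB3 (0.10) changed sign. None of these values was called (limma adjusted p = 0.494, 0.806, 0.217 and 0.786). The cause was not tested for these, beyond the use of another probe set for those genes and of fewer arrays in the fits without 1 array. Of the results for named genes under the planned settings other than leaving out an array, 694 were the same. Another 23 lost their call with the sign kept, 12 gained it, and 4, those named above, changed sign and lost their call. Of the list results under those settings, 303 were the same, 36 lost their call and 6 gained it. No detection calls were used, so the signal over background of dim genes is unknown, and their fold changes can be too small.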

Other observations

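The genes of this part, and its tests of control replicate 2, of the histone genes and of chromosome segments, were chosen after the results were seen. Beyond HLA-DRA, HLA-DPA1, HLA-DMA, HLA-DQA1 and CD74, the class II genes HLA-DMB (log2 -1.23 ± 0.16 SE, limma adjusted p = 0.00463) and HLA-DPB1 (-0.44 ± 0.08, adjusted p = 0.0205) also fell in knockdown cells, in 3 of 3 arrays and under both scalings tried. HLA-DOA (-0.99 ± 0.28, adjusted p = 0.0662) and CIITA, the transactivator of class II genes (0.09 ± 0.09, adjusted p = 0.632), were not called. CIITA measured 3.7 to 4.5 in intensity, below the median gene at 8.68, where RMA compresses folds, so a change could be missed. HLA-DMB kept its call in all 6 fits without 1 array, and HLA-DPB1 in 1 of them (-0.46 to -0.38). Without probe sets ending in _x_at or _s_at, which can bind several transcripts, HLA-DMB (-0.27, adjusted p = 0.24), HLA-DPB1 (-0.094, adjusted p = 0.711) and HLA-DRA (0.14) were not called, CD74 (-0.96) and HLA-DMA (-0.93) were, and HLA-DPA1 and HLA-DQA1 had no other probe set.

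Other genes looked up after the falls of TFAP2B and CDH19 were seen went both ways. The receptor phosphatase PTPRZ1 was 3.74-fold lower (log2 -1.90 ± 0.17 SE, limma adjusted p = 0.000785), the transcription factor FOXD3 3.41-fold lower (-1.77 ± 0.15) and the calcium-binding protein S100B 2.48-fold lower (-1.31 ± 0.15), each called in all 6 fits without 1 array, with PTPRZ1 at -1.09 without probe sets ending in _x_at or _s_at. The transcription factor SOX10 fell by 0.54 ± 0.11 and kept its call in 1 of those fits (-0.66 to -0.45), while SOX9 rose 3.13-fold (1.65 ± 0.14, adjusted p = 0.000785). GFRA1 (-0.16 ± 0.11, adjusted p = 0.434), TFAP2A (0.06 ± 0.08, adjusted p = 0.739), NGFR (0.09 ± 0.08, adjusted p = 0.557) and L1CAM (0.12 ± 0.09, adjusted p = 0.464) were not called. These genes were not tested as a set.

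Control replicate 2 lay towards the knockdown arrays on several gene lists. Its MAP4K5 level was 1.9954 above the knockdown mean on the log2 scale, which argues against a knockdown array or knockdown RNA under the control label. On a scale from the other controls at 0 to the knockdown arrays at 1, it stood at 0.9632 on the stress response list (95% bootstrap interval over genes 0.858 to 1.08). In this 1 array the list thus stood near the knockdown level with MAP4K5 at the control level. Whether loss of MAP4K5 was the only cause of that shift stays open, since 1 array cannot decide it. The question was drawn from these same levels, and the interval does not cover the spread between arrays. Control replicate 2 stood at 0.9719 on the DNA replication list. A growth or stress state that differed between cultures apart from MAP4K5 is a candidate explanation that stays open. It was drawn from these same levels and no other value tests it. The position on the hypoxia and glycolysis list, 0.04, had an interval of -2.996 to 0.54.

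Of 73 measured histone genes, 6 rose and 1 fell in the knockdown arrays, and the rest were not called. H2BC5, H2BC12, H1-2 (1.82 ± 0.09), H2AC6 (1.02 ± 0.11), H2AX (0.72 ± 0.15) and H2BC21 (0.67 ± 0.11) rose and H1-10 fell (-0.35 ± 0.08), each under both scalings tried. H2AX and H1-10 were called in 1 and H2BC21 in 4 of the 6 fits without 1 array, and H1-10 stood at -0.043, not called, without probe sets ending in _x_at or _s_at. In control replicate 2, whose replication genes stood at the knockdown level, the 6 that rose lay at a median of -1.3786 relative to the knockdown mean (range -1.97 to -0.36). These 6 genes were picked by a test that counted control replicate 2 as a control, and their groups did not overlap. A negative value was therefore fixed in advance, and it comes from 1 array, so a larger share of cells in S phase stays open. Signal shared between near-identical copies also stays open. Of the 6 genes, 2 were read by probe sets ending in _s_at or _x_at, and the probe sequences were not used here.

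A gain or loss of a long chromosome segment was tested as a source of the changed genes. Among 357 windows of 25 neighbouring bright genes the largest median log2 fold change was 0.2144 in size. Of 1000 shufflings of the gene order, 561 gave a value as large. The largest median argues against a segment with a shift over 0.3 that fills a whole window. The windows did not overlap, so a segment of 25 genes across a window boundary need not move any median that far. A segment placed in that way stays open.

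Only 10 splits of the 6 arrays into 3 against 3 exist, too few for a share under 0.05. The real split gave 1420 genes, 179 genes of at least 2-fold and 10 lists, each reached in 1 of the 10 splits, and the highest of the other splits gave 0, 0 and 9. The splits with 7 to 9 lists set controls 1 and 3 with 1 knockdown array against control 2 with the others, which points to the structure of the arrays described for control replicate 2. By limma these splits called 0 genes after adjustment and 1021 to 1414 at an unadjusted p under 0.05, against 4256 for the real split.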
